A study of Mus musculus with 12 samples.

How the data were processed

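Total RNA of the gastrocnemius muscle was extracted with Trizol, made into biotinylated cRNA and hybridised to Affymetrix mouse arrays, per the labels. The 12 arrays came from 4 groups of 3: young wild-type (WT_young), young knock-out (KO_young), old wild-type (WT_old) and old knock-out (KO_old), where knock-out means a muscle-specific deletion of Ppargc1a by a myogenin-driven cre. The labels name no batch, sex or litter, and the replicate numbers are names that carry no order and pair no arrays. The values deposited by the authors are log2 signals made with RMA in the affy package, per the submitters' processing notes, which give no version. The values were used as deposited, without a further normalization.

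Each array held 45101 probe sets, 64 of them controls. Of the 45101, 34958 named 1 gene, 932 several and 9211 none, and 34754 named a gene of the mouse RefSeq table (GRCm38.p6), which served for names and neighbours alone. Each of the 18194 genes was tested with 1 probe set, the one with the highest mean over the 12 arrays, and 9012 genes had more than 1. The fixed signal floor for named genes was the median log2 of the probe sets, 6.22. The lowest deposited value was about log2 3.2 and the highest about 16.0, so small changes in dim genes lie in the background of the arrays. Where the lower group mean lies under 6.22, a fold is given as "at least" and the log2 difference is a lower bound in size, since background compresses both.

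Limma 3.58.1 in R 4.3.3 fitted 4 group means to the 12 arrays (lmFit and eBayes, 8 residual degrees of freedom, 4.15 prior degrees of freedom), and p-values were adjusted by Benjamini and Hochberg over genes, with a threshold of 0.05. The comparisons were knock-out minus wild-type in young and in old muscle, old minus young in wild-type and in knock-out muscle, and the difference of the 2 genotype effects (interaction). Each test rests on 3 arrays per group. Gene lists, written from general knowledge with the comparisons, thresholds and other settings before the data were examined, were tested with camera at a correlation of 0.01 between genes, adjusted over the 31 lists with 5 or more measured genes. The sex-linked list had 4 and is given gene by gene. Beside it stand camera with an estimated correlation and fry, whose directional p tests movement 1 way and whose mixed p tests movement either way, neither relative to other genes. List scores are the mean over a list's genes of log2 minus the young wild-type mean.

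Genes are named by a fixed rule: Ppargc1a on all probe sets, and per comparison the 10 largest rises and 10 largest falls among genes past the threshold whose groups do not overlap and whose higher group mean reaches the floor. Genes without a proper name were passed over (0, 4, 9 and 45 in the 4 comparisons). Where fewer than 5 genes passed, the 10 smallest p-values are named. For each list described, up to 4 members with the smallest p are named.

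Overlaps were set beside the number that chance gives per direction from the 2 counts and the number of genes. Because the age effect in wild-type muscle and the genotype effect in young muscle share the young wild-type arrays, their correlation was set beside 100 simulated draws without effects. In these draws the genes varied independently.

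The procedure was tested on simulated data with shifts of 0.5, 1 and 2 log2 given to 67, 67 and 66 genes. It recovered 38.8%, 95.5% and 98.5% of them for genotype in young muscle, 41.8%, 94.0% and 100% for genotype in old muscle, 52.2%, 97.0% and 98.5% for age in wild-type muscle, 43.3%, 94.0% and 100% for age in knock-out muscle and 7.46%, 80.6% and 98.5% for the interaction. False calls were 10 of 165, 11 of 168, 10 of 175, 13 of 171 and 3 of 127. A list of 30 genes shifted by 0.3 gave a camera adjusted p of 6.46e-18 (0.000220 with an estimated correlation), and 0 unshifted lists were called. The simulated genes varied independently and the lists were random. The simulation therefore cannot show how often camera calls unshifted lists whose genes vary together.

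The alternatives were testing every probe set, the mean of a gene's probe sets, only brighter genes, centring arrays on their median, quantile normalization again, trended and robust variances, array weights, only the groups compared, an adjusted p of 0.10 and leaving out each array. Leaving out KO_old 1 and WT_young 1 together was added after the data were seen. Probe sets that name no gene or several were left out of the gene tests and tested apart.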

Results

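Gene expression was compared in the gastrocnemius, a calf muscle of mixed fibre type, between wild-type mice and mice labelled as muscle-specific knock-outs of Ppargc1a, the gene of the coactivator PGC-1alpha that drives mitochondrial gene expression. Young (10 week) and old (24 month) muscle of both genotypes made 4 groups of 3 arrays, 12 arrays with 45101 probe sets each. Each of 18194 genes was tested with 1 probe set. Array medians lay between log2 6.19 and 6.25, and replicate numbers carry no order. The labels do not say that the arrays came from separate animals, so the p-values measure the spread between these samples, which may be partly technical. Values after ± are standard errors from limma unless an SD is named, and 3 arrays per group limit their precision.

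Ppargc1a was not lower in the arrays labelled knock-out on any of its 5 probe sets. On the brightest, young wild-type arrays read log2 10.8, 11.2 and 11.2, young knock-out arrays 11.1, 11.5 and 12.1, old wild-type arrays 12.1, 11.8 and 11.5, and old knock-out arrays 12.1, 11.8 and 12.3. Knock-out minus wild-type was 0.47 ± 0.22, 0.49 ± 0.24, 0.58 ± 0.24, 0.42 ± 0.24 and 0.53 ± 0.23 for the 5 probe sets in young muscle (n = 3 per group, smallest adjusted p = 0.439). These RNA differences did not pass. Read as a lower RNA signal, the deletion named in the labels and the loss named in the series title have the opposite direction. In old muscle the same differences were 0.49, 0.44, 0.30, 0.30 and 0.29 (adjusted p from 0.283 to 0.559). The labels do not give the deleted exons, and a probe set that lies outside them checks nothing about genotype, so "knock-out" below means the arrays labelled so. Ppargc1a was also not lower in old muscle: old minus young wild-type was 0.44, 0.44, 0.88, 0.48 and 0.75, and did not pass (smallest adjusted p = 0.0751). For that Ppargc1a probe set leaving out KO_young 3 gave 0.0380, and the settings run ranged from 0.0209 to 0.226. In knock-out muscle the age differences were 0.45, 0.39, 0.61, 0.35 and 0.51 (smallest adjusted p = 0.145). The genotype differences at the 2 ages were 0.01, -0.05, -0.27, -0.13 and -0.24 apart, and none of these passed.

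**Figure D1:**
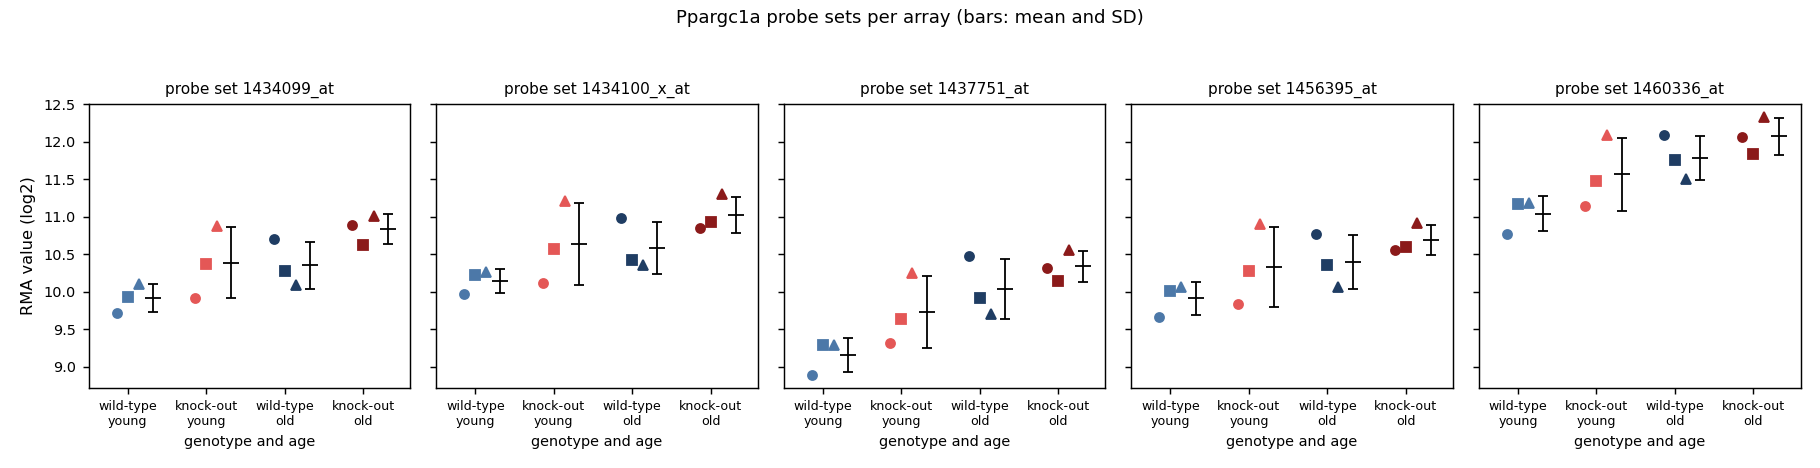
RMA log2 values of the 5 Ppargc1a probe sets in every array, 1 panel per probe set, with bars for group mean and SD (n = 3). On the brightest probe set, 11.6 and 12.1 in the knock-out groups lay above the wild-type means of the same age.

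Xist, the female-specific silencing RNA, stayed between log2 4.85 and 5.48 in the 12 arrays. The Y-linked Eif2s3y stayed between 10.2 and 11.2, Kdm5d between 7.41 and 8.27 and Uty between 7.12 and 8.36. Arrays within a group correlated at 0.989 to 0.996. KO_old 1 lay apart from its replicates, with 42.6 on the first principal component (37.8% of variance) beside 19.3 and 15.7. WT_young 1 carried a lymphocyte marker score of 0.570 beside -0.258 and -0.312 in its replicates, with macrophage, interferon and matrix scores of 0.386, 0.289 and 0.284. The 18S ribosomal RNA control probes averaged 13.8, 13.8 and 13.9 in young wild-type, 14.2, 13.2 and 13.8 in young knock-out, 12.3, 11.7 and 12.2 in old wild-type and 12.8, 12.8 and 11.7 in old knock-out arrays, so they moved with age. The 5' minus 3' signal of Actb averaged -0.289, -0.199, -0.129 and -0.0143 in these 4 groups and that of Gapdh -0.193, -0.171, -0.0270 and -0.0208, and these too moved mostly with age.

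Young knock-out muscle had less Kcng4, a potassium channel subunit gene, than young wild-type muscle (3.79-fold lower, log2 -1.92 ± 0.28, adjusted p = 0.0232, n = 3 per group). Glrx, whose product reduces glutathione-bound proteins, was 2.40-fold lower (-1.26 ± 0.10, adjusted p = 0.000620), and its other probe set gave -1.24. Fndc5, the precursor gene of the secreted peptide irisin, fell 2.04-fold (-1.03 ± 0.17, adjusted p = 0.0360) and Cox7a1, the muscle form of a cytochrome c oxidase subunit, 1.90-fold (-0.93 ± 0.14, adjusted p = 0.0306). The enzyme genes Phyh, of the peroxisome (-1.03 ± 0.12), Clybl, of the mitochondrion (-0.96 ± 0.13), and Aspa, of the cytosol (-1.01 ± 0.13), also fell. So did Car2, a carbonic anhydrase gene (-1.05 ± 0.13), the fucose enzyme gene Fuom (-1.10 ± 0.12) and Hsbp1l1 (-1.15 ± 0.19, a lower bound in size, since its lower mean lay under 6.22). Fewer genes rose, among them Tph1, which makes serotonin's precursor (at least 1.96-fold, 0.97 ± 0.12, adjusted p = 0.00909), and the chaperone gene Hspa1l (1.53-fold, 0.62 ± 0.10, adjusted p = 0.0341). The signalling scaffold gene Arrb1 (0.78 ± 0.13), Lrp11 (0.70 ± 0.12), Lonrf1 (0.51 ± 0.09) and Psip1 (1.13 ± 0.19, although its other 2 probe sets gave 0.03 and 0.04) rose as well. In total 35 genes passed limma, 7 up and 28 down, while 2049 had an unadjusted p under 0.05 and 20.8% had groups that did not overlap (10% by chance).

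Mitochondrial enzyme genes as lists were lower in young knock-out muscle. Of 18 measured genes of the tricarboxylic acid cycle, which oxidises acetyl groups, 1 fell, 0 rose and 17 did not pass (17 fell when adjusted over the list alone), with a median of -0.38 (camera adjusted p = 8.61e-20, adjusted p = 0.213 with an estimated correlation). Dld passed (-0.50 ± 0.08, adjusted p = 0.0341), and Dlat gave -0.63 ± 0.11 without passing (adjusted p = 0.0519). For complexes II to IV of the respiratory chain, 1 of 29 genes fell (Cox7a1; 22 over the list alone, median -0.29, adjusted p = 7.25e-17, adjusted p = 0.251 with an estimated correlation). Complex I had 0 of 34 past the test, 18 lower over the list alone and a median of -0.25 (adjusted p = 2.01e-17, adjusted p = 0.313 with an estimated correlation). Ndufv1 was at -0.44 ± 0.08 (adjusted p = 0.0560). ATP synthase had 1 of 16 lower, the ring subunit gene Atp5g1 (-0.60 ± 0.10, adjusted p = 0.0390), 12 over the list alone and a median of -0.23 (adjusted p = 1.71e-11, adjusted p = 0.251 with an estimated correlation). Fatty acid oxidation had 0 of 23 past the test (8 lower over the list alone, Etfa -0.40 ± 0.08), median -0.27 (adjusted p = 8.17e-11, adjusted p = 0.251 with an estimated correlation). The mitochondrial ribosome had 0 of 57 past the test (7 lower over the list alone, Mrpl15 -0.43 ± 0.08), median -0.13 (adjusted p = 4.36e-09, adjusted p = 0.251 with an estimated correlation).

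Lists outside energy metabolism moved in both directions. Mitochondrial dynamics had 1 of 19 lower, the fusion gene Mfn1 (-0.75 ± 0.11, adjusted p = 0.0160), 4 over the list alone and a median of -0.09 (adjusted p = 0.0107, adjusted p = 0.313 with an estimated correlation). The dynamics list was not called without WT_young 3 (0.0650) or KO_young 1 (0.109). Neuromuscular junction and denervation-responsive genes were higher (0 of 28 past the test, 5 up and 1 down over the list alone, median 0.15, adjusted p = 0.0327, adjusted p = 0.251 with an estimated correlation). The acetylcholine receptor gene Chrna1 was at 0.51 ± 0.09 (adjusted p = 0.0560) and did not pass. The neuromuscular junction list lost its call without WT_young 1 (0.136) or KO_young 3 (0.125). Lymphocyte markers were lower (0 of 20 past the test, 1 over the list alone, Cd8a -0.42 ± 0.10, median -0.30, adjusted p = 0.000786, adjusted p = 0.378 with an estimated correlation). That call ended without WT_young 1 (0.458), the array high in these markers. Schwann cell markers (0 of 14 past the test or over the list alone, median -0.22, adjusted p = 0.00396) and endothelial and angiogenesis genes (0 of 25 and 1 lower over the list alone, Vegfb, median -0.13, adjusted p = 0.00428) were lower, each with adjusted p = 0.378 with an estimated correlation. The endothelial call ended without WT_young 1 (0.165) or KO_young 2 (0.139). Heat shock genes were higher (0 of 30 past the test or over the list alone, median 0.07, adjusted p = 0.00710, adjusted p = 0.378 with an estimated correlation). That call ended without KO_young 3 (0.159). Extracellular matrix genes were higher (0 of 38 past the test or over the list alone, median 0.24, adjusted p = 0.00710, adjusted p = 0.767 with an estimated correlation). They lost the call without WT_young 2 (0.0792) or WT_young 3 (0.0942) and turned to -0.0250 without KO_young 3.

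Camera thus called 13 of 31 lists in young muscle, 3 up and 10 down, while camera with an estimated correlation called 0 and fry 8. Both forms of fry ended the Schwann, endothelial, matrix, heat shock and lymphocyte calls. Testing brighter genes alone ended the matrix (0.103), heat shock (0.0802) and neuromuscular junction calls (0.0814), quantile normalization again the neuromuscular junction call (0.0679) and the mean of probe sets the mitochondrial dynamics call (0.0559). Among lists not called, the mitochondrial biogenesis regulators had Esrra, a nuclear receptor that works with PGC-1alpha, at -0.75 ± 0.14 (adjusted p = 0.0593), with a median of -0.02 for the list (adjusted p = 0.280). The antioxidant gene Sod2 (-0.55 ± 0.09, adjusted p = 0.0322) and the calcium-binding gene S100a1 (-0.88 ± 0.10, adjusted p = 0.00481) fell while their lists had medians of 0.00 and 0.10 and were not called. The interferon list, with a median of -0.06 (adjusted p = 0.575), reached 0.0886 (adjusted p = 0.0425) without WT_young 1. The count of 35 genes (20.0% up) became 1019 with array weights (38.4% up), 104 with trended and robust variances, 65 with brighter genes alone, 56 with quantile normalization again and 119 at an adjusted p of 0.10. Leaving out KO_old 1 and WT_young 1 together, chosen after seeing the data, gave 216. It was 173 without KO_old 1, 7, 7 and 8 without KO_young 1, 2 and 3, 16, 15 and 13 without WT_old 1, 2 and 3, 7 without WT_young 2 and 1 without WT_young 3. Glrx was the 1 named gene that passed in each setting run.

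Old knock-out muscle had at least 4.40-fold less Kcng4 than old wild-type muscle (-2.14 ± 0.28, adjusted p = 0.00775, n = 3 per group) and at least 4.77-fold less Slc15a5, a peptide transporter family gene (-2.25 ± 0.36, adjusted p = 0.0129). Fndc5 was 3.06-fold lower (-1.61 ± 0.17, adjusted p = 0.00154), Cox7a1 2.60-fold lower (-1.38 ± 0.14, adjusted p = 0.00154) and Ckmt2, the mitochondrial creatine kinase gene of muscle, 2.30-fold lower (-1.20 ± 0.11, adjusted p = 0.000865). The fission gene Mtfp1 (-1.33 ± 0.21), Lynx1, which tempers acetylcholine receptors (-1.25 ± 0.26), Phyh (-1.25 ± 0.12), Clybl (-1.18 ± 0.13) and Iqsec2 (-1.41 ± 0.20, other probe sets -0.24 and -0.03) fell too. The macrophage lysosome gene Cd68 rose 4.51-fold (2.17 ± 0.41, adjusted p = 0.0256) and Tecrl, an endoplasmic reticulum enzyme gene of striated muscle, at least 3.92-fold (1.97 ± 0.36, adjusted p = 0.0252). Ndrg4 (1.64 ± 0.24, adjusted p = 0.0106) and the lipid carrier gene Apoe (1.22 ± 0.27, adjusted p = 0.0476) rose too. Bhlhb9 (1.26 ± 0.22), Tceal8 (1.12 ± 0.16), the channel gene Panx1 (1.07 ± 0.19), the cytokine subunit gene Il12a (1.02 ± 0.16), Armh4 (1.02 ± 0.20) and Scn3b (1.09 ± 0.18, other probe set -0.15) also rose. Eif2s3y was 0.68 higher in old knock-out muscle (adjusted p = 0.0121). In total 241 genes passed limma, 86 up and 155 down (35.7% up, and 48.5% of 237 with each array centred on its median), while 3505 had an unadjusted p under 0.05 and 23.8% had groups apart (10% by chance).

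More mitochondrial genes passed one by one in old than in young muscle. The adjusted threshold is looser where more genes pass, and 241 genes passed in old muscle against 35 in young muscle. Adjusted over the list alone, the tricarboxylic acid cycle and mitochondrial ribosome lists had fewer lower genes in old than in young muscle. Complex I, complexes II to IV, ATP synthase and fatty acid oxidation had more. In the tricarboxylic acid cycle list 13 of 18 fell and 0 rose (15 over the list alone, median -0.46, camera adjusted p = 6.99e-18, adjusted p = 0.297 with an estimated correlation). Dlat was at -0.98 ± 0.11 (adjusted p = 0.00220) and Pdha1 at -0.53 ± 0.08 (adjusted p = 0.0111). Complexes II to IV had 12 of 29 lower (26 lower and 1 higher over the list alone, median -0.38, adjusted p = 3.01e-19, adjusted p = 0.307 with an estimated correlation), among them Cox10 (-0.68 ± 0.10) and Sdha (-0.56 ± 0.09). Complex I had 7 of 34 lower (28 over the list alone, median -0.35, adjusted p = 3.52e-19, adjusted p = 0.359 with an estimated correlation), such as Ndufa8 (-0.75 ± 0.12) and Ndufs1 (-0.67 ± 0.12). ATP synthase had 6 of 16 lower (14 over the list alone, median -0.33, adjusted p = 4.13e-12, adjusted p = 0.359 with an estimated correlation), such as Atp5g1 (-0.71 ± 0.10). Fatty acid oxidation had 2 of 23 lower, Acaa2 (-0.82 ± 0.17) and Hadh (-0.42 ± 0.09), 9 over the list alone and a median of -0.21 (adjusted p = 0.000265, adjusted p = 0.475 with an estimated correlation). This list also covers fatty acid uptake and names Lpl and Lipe, as the adipocyte list does. KO_old 1, with an adipocyte score of 1.17, scored -0.0133 on it beside -0.273 and -0.196 in its replicates. The mitochondrial ribosome had 1 of 57 lower, Mrpl45 (-0.35 ± 0.07), 4 over the list alone and a median of -0.08 (adjusted p = 0.00540, adjusted p = 0.565 with an estimated correlation). The list was not called without KO_old 1 (0.153). Of the biogenesis regulators Esrra (-0.91 ± 0.14), the mitochondrial deacetylase gene Sirt3 (-0.91 ± 0.18) and Perm1 (-0.93 ± 0.19) fell, although the list did not pass (median -0.05, adjusted p = 0.170). Sod2 (-0.65 ± 0.09), Mfn1 (-0.62 ± 0.11), S100a1 (-0.98 ± 0.10) and the calcineurin inhibitor gene Rcan2 (-1.06 ± 0.15) fell within lists that were not called.

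Macrophage markers were higher in old knock-out muscle, with 1 of 33 up (Cd68; 6 over the list alone) and a median of 0.50 (camera adjusted p = 8.45e-07, adjusted p = 0.475 with an estimated correlation). Csf1r, the receptor gene for a macrophage growth factor, gave 0.68 ± 0.19 without passing (adjusted p = 0.0899). The macrophage scores overlapped, at 0.422, 0.551 and 0.954 in old knock-out and -0.244, 0.613 and -0.0009 in old wild-type arrays. Adipocyte markers had a median of 0.72 with 0 of 19 past the test or over the list alone (adjusted p = 0.000126, adjusted p = 0.475 with an estimated correlation). Their array scores were 1.17, 0.741 and -0.645 in old knock-out and -0.442, -0.553 and -0.0582 in old wild-type muscle, and Adipoq gave 2.10 ± 0.77 (adjusted p = 0.172). Atrophy and proteolysis genes were higher (0 of 26 past the test or over the list alone, median 0.27, adjusted p = 0.000153, adjusted p = 0.475 with an estimated correlation). The lysosomal protease gene Ctsl was at 0.99 ± 0.26 (adjusted p = 0.0841), and KO_old 1 scored 0.805 beside 0.186 and 0.206. Heat shock genes were higher (0 of 30 past the test or over the list alone, median 0.15, adjusted p = 0.000265, adjusted p = 0.359 with an estimated correlation). Hspb1 was at 0.50 ± 0.14. Slow fibre genes were higher too (0 of 18 past the test, 2 up over the list alone, median 0.32, adjusted p = 0.00119, adjusted p = 0.359 with an estimated correlation). The Z-disc gene Csrp3 was at 0.84 ± 0.21 (adjusted p = 0.0724). Endothelial and angiogenesis genes were lower (1 of 25 fell, the growth factor gene Vegfb at -0.92 ± 0.14, 2 over the list alone, median -0.22, adjusted p = 0.00715, adjusted p = 0.475 with an estimated correlation). Glycolysis genes were lower as well (1 of 27 fell, Pdk2, a brake on pyruvate oxidation, at -0.64 ± 0.12, and 1 over the list alone, median -0.15, adjusted p = 0.0188, adjusted p = 0.475 with an estimated correlation). The list lost its call without WT_old 2 (0.0530) or KO_old 1 (0.121).

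In old muscle camera called 13 of 31 lists, 5 up and 8 down, camera with an estimated correlation 0 and fry 4. Directional fry ended the adipocyte, macrophage, atrophy, heat shock, slow fibre, fatty acid oxidation, mitochondrial ribosome, endothelial and glycolysis calls, and mixed fry the adipocyte, macrophage and atrophy calls. Lists that did not pass included interferon response (median 0.15, adjusted p = 0.0520), extracellular matrix (0.03, adjusted p = 0.662), lymphocyte (-0.04, adjusted p = 0.396) and neuromuscular junction (-0.03, adjusted p = 0.723). The count of 241 genes became 0 when limma was run on the 6 old arrays alone, 389 with trended and robust variances, 372 with brighter genes alone and 800 at an adjusted p of 0.10. Without KO_old 1, 2 and 3 it was 151, 95 and 644, without KO_young 2 and 3 it was 136 and 160, without WT_old 1, 2 and 3 it was 109, 39 and 28, and without WT_young 3 it was 121.

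At both ages 25 genes passed in the same direction, 24 of them lower with the knock-out. Kcng4, Fndc5, Glrx, Cox7a1, Phyh, Clybl, Ckmt2, Mfn1, Atp5g1, Sod2 and Dld were among those that fell in young and old muscle. Hspa1l (0.62 young, 0.58 old) was the 1 that rose in both. Chance overlap would give 0.239 genes down and 0.0331 up, and 0 genes passed in opposite directions. Ckmt2 (-0.69 young, -1.20 old), the haem enzyme gene Alas1 (-0.54, -0.70), Fdx1 (-0.56, -0.51) and the amino acid enzyme genes Got1 (-0.75, -0.76) and Got2 (-0.80, -0.85) are named from this overlap after the values were seen. Across 18194 genes, which are not independent replicates, the log2 differences at the 2 ages correlated with Pearson 0.394 and Spearman 0.426. Of the 35 young calls 32 had the same sign in old muscle, and of the 241 old calls 225 had the same sign in young muscle. The overlap of 25 became 44 with brighter genes alone and 39 with quantile normalization again. It was 61 without KO_old 1, 6, 7 and 8 without KO_young 1, 2 and 3, 12, 12 and 9 without WT_old 1, 2 and 3, 6 without WT_young 2 and 1 without WT_young 3.

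**Figure D2:**
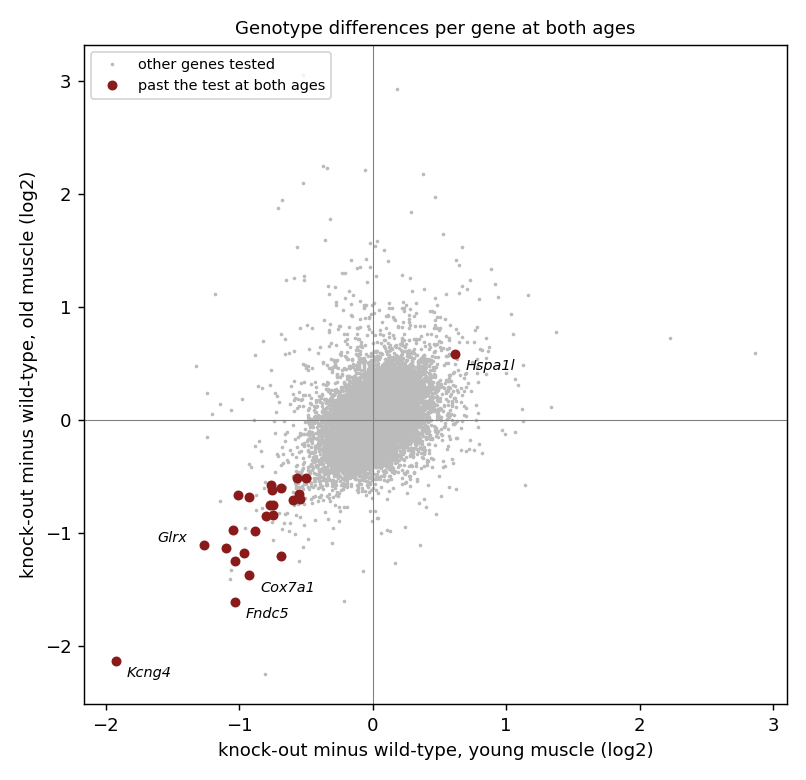
Knock-out minus wild-type log2 difference per gene in young (horizontal) and old (vertical) muscle, with the 25 genes that passed at both ages in red. Kcng4 (-1.92, -2.14), Fndc5 (-1.03, -1.61) and Cox7a1 (-0.93, -1.38) lie at the lower left and Hspa1l at the upper right.

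No gene passed limma for a genotype effect that differed between the ages, with 992 at an unadjusted p under 0.05 and a smallest adjusted p of 0.236. In the simulated data this test recovered 7.46% of shifts of 0.5 log2 and 80.6% of shifts of 1, so small differences could be missed. Leaving out KO_old 3 gave 37 genes (91.9% risen) and leaving out WT_old 2 gave 1. The smallest p-values belonged to Trim14, an antiviral signalling gene (0.86 ± 0.13, adjusted p = 0.236, n = 3 in each of 4 groups, other probe set -0.16) and Hmga2-ps1 (-1.31 ± 0.20, adjusted p = 0.236), which did not pass. Neither did Tph1 (-1.06 ± 0.17, adjusted p = 0.267) or the survival gene Bcl2 (-0.74 ± 0.13, adjusted p = 0.508, 4 other probe sets from -0.42 to 0.84). Prkcd (-0.86 ± 0.17), Frzb (-1.11 ± 0.23), Nkain2 (0.58 ± 0.13), Mir133b (1.25 ± 0.27), Prkg2 (-0.54 ± 0.12) and Eif2s3y (0.68 ± 0.15) followed, each with adjusted p = 0.871. All group means of Trim14 (5.28 to 6.03) and Nkain2 (4.34 to 4.87) lay under 6.22, where background limits small changes. Some group means of Tph1, Frzb and Mir133b lay under it too. With the 12 arrays the differences between old and young calls above are therefore not shown gene by gene.

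Adipocyte genes had a higher knock-out effect in old than in young muscle as a list, with a median of 1.10 over 19 genes (camera adjusted p = 4.53e-08, adjusted p = 0.673 with an estimated correlation). Fabp4, a fatty acid carrier gene, gave 1.04 ± 0.35 without passing. In the 11 lists camera called, 0 members passed the test. Macrophage markers had a median of 0.32 (adjusted p = 0.00117) with Cd68 at 1.80 ± 0.57, atrophy genes 0.21 (0.00237) with Ctsl at 0.87 ± 0.37, and interferon genes 0.16 (0.0283), each with adjusted p = 0.673 with an estimated correlation. Slow fibre (0.11, 0.0334) and antioxidant genes (0.10, 0.0334) were higher too, with adjusted p = 0.673 with an estimated correlation for both. In the slow list 3 members rose when adjusted over the list alone, with Csrp3 at 1.33 ± 0.30. Complexes II to IV (-0.11, 0.00404), glycolysis (-0.11, 0.00437), complex I (-0.10, 0.0143) and calcium handling (-0.12, 0.0334) were lower with adjusted p = 0.673 with an estimated correlation. Neuromuscular junction and denervation-responsive genes (-0.19, 0.0332) were lower with adjusted p = 0.561 with an estimated correlation. Camera with an estimated correlation and both forms of fry called 0 lists. The antioxidant call also ended with the mean of probe sets (0.0604), brighter genes alone (0.0684) and quantile normalization again (0.0551), the calcium call with the mean of probe sets (0.0673) and the slow fibre call with brighter genes alone (0.0531). The atrophy (0.152), antioxidant (0.376), calcium (0.438), complex I (0.920) and complexes II to IV (0.200) calls ended without KO_old 1.

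Without WT_young 1 the interaction calls of the interferon (0.796), macrophage (0.0624), neuromuscular junction (0.0624), complex I (0.0688) and slow fibre (0.162) lists ended. The antioxidant call also ended without WT_young 2 (0.0651), KO_young 1 (0.0504), KO_young 2 (0.0702) or WT_old 3 (0.0604), and the calcium call without WT_young 2 (0.0697), KO_young 2 (0.0894) or WT_old 3 (0.0604). The interferon call ended without KO_young 1 (0.0666), WT_old 1 (0.127), WT_old 3 (0.0604) or KO_old 3 (0.0823), and the macrophage call without KO_young 1 (0.0666), WT_old 1 (0.0789) or KO_old 3 (0.130). The neuromuscular junction call ended without WT_young 2 (0.0593), KO_young 3 (0.0747) or KO_old 3 (0.0823), and the slow fibre call without KO_young 1 (0.0891), WT_old 2 (0.289) or KO_old 2 (0.240). The adipocyte and glycolysis calls held without any 1 array.

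**Figure D3:**
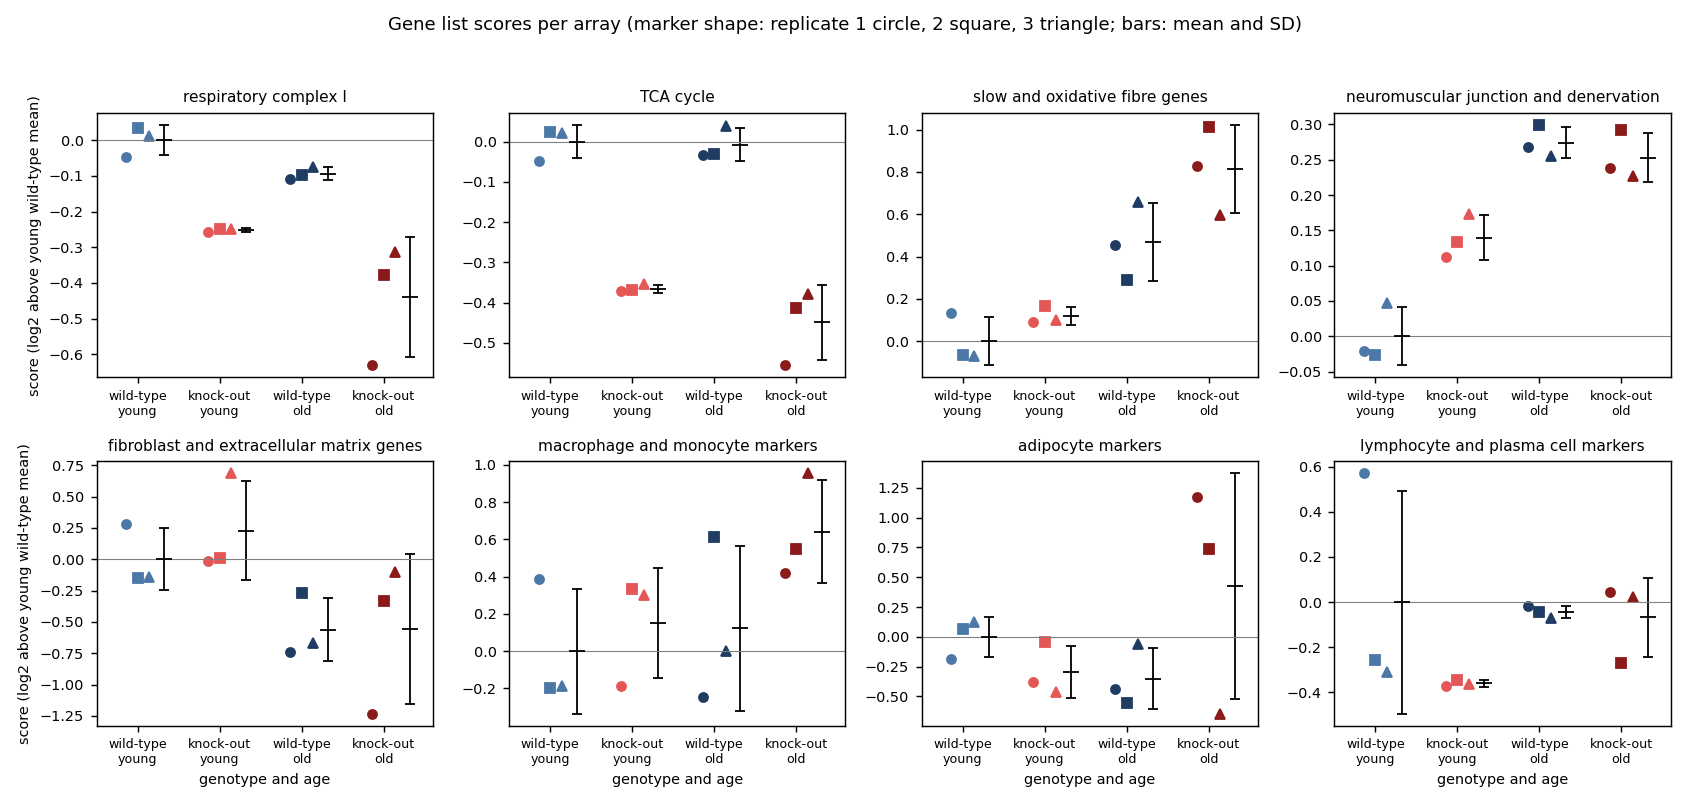
Mean log2 above young wild-type of the genes of 8 lists in every array, by group, with bars for mean and SD (n = 3). Complex I scores were -0.258, -0.248 and -0.249 in young knock-out and -0.631, -0.378 and -0.312 in old knock-out arrays, whereas adipocyte scores in old knock-out arrays spread from -0.645 to 1.17.

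Old wild-type muscle had 14.4-fold more Sln, the gene of the calcium pump regulator sarcolipin, than young wild-type muscle (3.85 ± 0.71, adjusted p = 0.0131, n = 3 per group), although a dimmer probe set gave 0.10. The keratin gene Krt18 rose at least 7.37-fold (2.88 ± 0.43, adjusted p = 0.00473), Cpne2, a calcium-dependent membrane-binding gene, 7.20-fold (2.85 ± 0.21, adjusted p = 4.34e-05) and the galectin gene Lgals3 5.76-fold (2.53 ± 0.31, adjusted p = 0.00177). The stress-responsive muscle gene Ankrd1 rose 5.39-fold (2.43 ± 0.18, adjusted p = 4.34e-05) and Myh3, the embryonic myosin heavy chain gene, 4.42-fold (2.14 ± 0.15, adjusted p = 4.32e-05). Rrad (2.82 ± 0.59), Ppp1r14bl (2.44 ± 0.23), Kcnab1 (2.38 ± 0.38) and Mib1 (2.14 ± 0.27) also rose. The corneal and tendon proteoglycan gene Kera fell at least 12.4-fold (-3.63 ± 0.41, adjusted p = 0.00106), the collagen gene Col1a1 7.54-fold (-2.91 ± 0.59, adjusted p = 0.0214) and the Wnt inhibitor gene Wif1 at least 7.03-fold (-2.81 ± 0.34, adjusted p = 0.00148). The genes Tnmd, known from tendon (-2.30 ± 0.38), Chad, known from cartilage (-2.23 ± 0.34), and Fmod, which binds collagen (-2.19 ± 0.42), fell too. Ifi27l2a (-2.38 ± 0.58), the imprinted RNA gene Rian (-2.32 ± 0.36, 3 other probe sets from -0.80 to -0.10, not called), Pon1 (-2.08 ± 0.24) and Vapb (-2.20 ± 0.11, other probe sets -0.10 and 0.07) fell as well. The lower means of Ppp1r14bl, Rrad, Rian and Pon1 lay under 6.22, so their differences are lower bounds in size. In total 659 genes passed limma, 300 up and 359 down, with 3017 at an unadjusted p under 0.05 and 26.2% with groups apart (10% by chance).

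Neuromuscular junction and denervation-responsive genes were higher in old wild-type muscle: 7 of 28 rose and 0 fell (8 up and 1 down over the list alone, median 0.08, camera adjusted p = 0.0168, adjusted p = 0.178 with an estimated correlation). Chrna1 (1.10 ± 0.09, adjusted p = 0.000122), Gadd45a (1.79 ± 0.29) and the receptor kinase gene Musk (1.08 ± 0.19) were among them. Heat shock genes had 4 of 30 up and 0 down (11 up and 2 down over the list alone, median 0.25, adjusted p = 0.000320, adjusted p = 0.372 with an estimated correlation). The chaperone genes Hspa1a (1.16 ± 0.26) and Hspa5 (0.46 ± 0.10) rose. Slow fibre genes had 1 of 18 up (2 over the list alone, median 0.29, adjusted p = 0.00215, adjusted p = 0.372 with an estimated correlation). Erythrocyte markers had 1 of 6 up, the haem synthesis gene Alas2 (1.08 ± 0.26), 2 over the list alone and a median of 0.32 (adjusted p = 0.00564, adjusted p = 0.178 with an estimated correlation). Extracellular matrix genes had 5 of 38 down and 1 up (12 down and 2 up over the list alone, median -0.49, adjusted p = 4.53e-05, adjusted p = 0.897 with an estimated correlation). The collagen-binding gene Sparc was at -1.51 ± 0.24 and Acta2 at 0.63 ± 0.15. Endothelial and angiogenesis genes had 3 of 25 down (4 over the list alone, median -0.17, adjusted p = 0.00564, adjusted p = 0.666 with an estimated correlation), namely Cdh5 (-0.76 ± 0.13), Pdgfrb (-0.86 ± 0.15) and Tie1 (-0.59 ± 0.15). Complex I (0 of 34 past the test or over the list alone, median -0.11, adjusted p = 0.0102, adjusted p = 0.897 with an estimated correlation) was lower. The list lost its call without WT_young 2 (0.0607). Complexes II to IV (0 of 29 past the test or over the list alone, median -0.08, adjusted p = 0.0290, adjusted p = 0.897 with an estimated correlation) were lower. The list lost its call without WT_young 2 (0.0652), WT_young 3 (0.0770) or WT_old 3 (0.0520).

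Several genes passed with age in wild-type muscle although their lists did not. The uncoupling protein gene Ucp3 (1.85 ± 0.22, adjusted p = 0.00128), Nqo1 (0.52 ± 0.12) and Srxn1 (0.59 ± 0.14) rose in the antioxidant list (median 0.05, adjusted p = 0.167). In the satellite cell and myogenic list Myog (0.90 ± 0.20) and the fusion gene Mymx (1.61 ± 0.39) rose and Myf5 (-0.75 ± 0.13) fell (median 0.01, adjusted p = 0.742). In the calcium list Camk2b (0.81 ± 0.10) and Cacng1 (0.55 ± 0.10) rose (adjusted p = 0.689). The insulin signalling genes Irs1 (-0.89 ± 0.19) and Slc2a4, which takes up glucose (-0.41 ± 0.10), fell (median -0.04, adjusted p = 0.327). The clock gene Nr1d1 fell (-0.74 ± 0.14, circadian list -0.09, adjusted p = 0.585). Eda2r, a p53-responsive receptor gene, rose (1.43 ± 0.27, senescence list median -0.04, mean 0.12, adjusted p = 0.688). The substrain marker Cyfip2 rose (1.41 ± 0.15, adjusted p = 0.000801, substrain list 0.10, adjusted p = 0.0776). In the interferon list Ifi27 (0.73 ± 0.10) and Gbp6 (1.27 ± 0.21) rose and Gbp7 (-1.37 ± 0.21) fell, with a median of -0.03 (adjusted p = 0.924) that turned to 0.0907 (adjusted p = 0.0446) without WT_young 1. Adipocyte (-0.27, adjusted p = 0.191), macrophage (0.03, adjusted p = 0.575), lymphocyte (-0.17, adjusted p = 0.575) and secreted-factor lists (median 0.07, mean -0.10, adjusted p = 0.771) were not called.

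Camera called 8 of 31 lists with age in wild-type muscle, 4 up and 4 down, camera with an estimated correlation 0 and fry 4, and without WT_young 1 camera called 13. Directional fry ended the matrix, endothelial, slow fibre, complex I and complexes II to IV calls, mixed fry those of complex I and complexes II to IV, and testing brighter genes alone that of complexes II to IV (0.0871). The count of 659 genes became 2451 with array weights, 1116 with every probe set tested, 1112 at an adjusted p of 0.10 and 1093 without KO_old 1. It was 352, 245 and 284 without WT_old 1, 2 and 3 and 346, 276 and 208 without WT_young 1, 2 and 3. The 18S probe sets were lower by -1.41, -1.78 and -2.01 (adjusted p = 0.0149, 0.00169 and 0.0234), a shift that moved with age beside these genes.

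Old knock-out muscle had 13.3-fold more Sln than young knock-out muscle (3.73 ± 0.71, adjusted p = 0.00719, n = 3 per group, dimmer probe set 0.48) and at least 9.72-fold more Krt18 (3.28 ± 0.43, adjusted p = 0.00109). It had 7.33-fold more Cd68 (2.87 ± 0.41, adjusted p = 0.00164), 7.18-fold more Ankrd1 (2.84 ± 0.18, adjusted p = 1.72e-05) and 5.40-fold more Atf3, a stress transcription factor gene (2.43 ± 0.41, adjusted p = 0.00384). Cpne2 (2.75 ± 0.21), the musculoskeletal gene Mustn1 (2.68 ± 0.25), Rhpn2 (2.50 ± 0.22), the plasma protein gene Orm1 (2.94 ± 0.84, adjusted p = 0.0447) and the antibody joining-chain gene Jchain (2.36 ± 0.63, adjusted p = 0.0346) also rose. Col1a1 fell 17.0-fold (-4.09 ± 0.59, adjusted p = 0.00194), Kera at least 16.1-fold (-4.01 ± 0.41, adjusted p = 0.000342) and Wif1 at least 15.2-fold (-3.93 ± 0.34, adjusted p = 0.000123). Chad (-3.41 ± 0.34), Fmod (-3.39 ± 0.42), Tnmd (-3.25 ± 0.38), Col1a2 (-2.96 ± 0.53, other probe sets -4.11 and -0.66), Comp (-2.77 ± 0.40), Col11a1 (-2.69 ± 0.32) and Nrep (-2.78 ± 0.52) fell as well. The lower means of Col11a1, Jchain and Rhpn2 lay under 6.22, so their differences are lower bounds in size. Old knock-out arrays spread widely for Orm1 (SD 2.30), Sln (SD 1.72), Nrep (SD 1.54) and Col1a2 (SD 1.31). Krt18 (SD 1.13), Col1a1 (SD 1.12) and Atf3 (SD 1.05) spread widely there too. The standard errors given pool the spread of the 4 groups and understate this. In total 1868 genes passed limma, 883 up and 985 down, with 4533 at an unadjusted p under 0.05, and 28.7% had groups apart (10% by chance).

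Slow fibre genes were higher with age in knock-out muscle, with 5 of 18 up and 0 down (8 over the list alone, median 0.44, camera adjusted p = 1.00e-05, adjusted p = 0.213 with an estimated correlation). Csrp3 (1.75 ± 0.21), Ankrd2 (1.46 ± 0.24) and the calcium store gene Casq2 (0.66 ± 0.14) rose. Heat shock genes had 9 of 30 up and 1 down (16 and 1 over the list alone, median 0.31, adjusted p = 3.50e-05, adjusted p = 0.267 with an estimated correlation). Hspa5 was at 0.55 ± 0.10 and Hspb1 at 0.72 ± 0.14. Atrophy and proteolysis genes had 4 of 26 up (12 over the list alone, median 0.32, adjusted p = 4.55e-05, adjusted p = 0.538 with an estimated correlation), the autophagy genes Sqstm1 (0.82 ± 0.13) and Gabarapl1 (1.48 ± 0.25) among them. KO_old 1 carried much of this rise, with an atrophy score of 0.805 beside 0.186 and 0.206 in its replicates. Antioxidant genes had 5 of 24 up (7 over the list alone, median 0.18, adjusted p = 0.000883, adjusted p = 0.212 with an estimated correlation), including Ucp3 (1.29 ± 0.22) and Gpx3 (0.94 ± 0.16). Erythrocyte markers had 4 of 6 up (4 over the list alone, median 0.52, adjusted p = 0.00163, adjusted p = 0.212 with an estimated correlation). Alas2 was at 1.37 ± 0.26 and the globin gene Hbb-b2 at 0.51 ± 0.13. Macrophage markers had 2 of 33 up, Cd68 and Lgmn (0.80 ± 0.20), 2 over the list alone and a median of 0.37 (adjusted p = 0.000246, adjusted p = 0.541 with an estimated correlation). Adipocyte markers had 0 of 19 past the test or over the list alone (Plin4 0.58 ± 0.18, median 0.73, adjusted p = 0.000632, adjusted p = 0.541 with an estimated correlation). KO_old 3 (-0.645) scored below the young knock-out arrays (-0.379, -0.046 and -0.460), and KO_old 1 and 2 at 1.17 and 0.741. Cytokines had 3 of 44 up (2 over the list alone, median 0.20, adjusted p = 0.00867, adjusted p = 0.538 with an estimated correlation). Interferon genes had 4 of 32 up and 1 down (5 and 1 over the list alone, median 0.13, adjusted p = 0.0489, adjusted p = 0.626 with an estimated correlation). Ifi27 was at 0.72 ± 0.10 and Gbp7 at -1.36 ± 0.21. The list lost its call without KO_young 1 (0.0897), KO_young 2 (0.0757), KO_old 2 (0.0748) or KO_old 3 (0.114).

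Matrix and respiratory chain genes were lower with age in knock-out muscle. Extracellular matrix genes had 10 of 38 down and 1 up (15 and 1 over the list alone, median -0.67, camera adjusted p = 4.43e-06, adjusted p = 0.541 with an estimated correlation). Sparc was at -1.61 ± 0.24 and Pi16, a fibroblast gene, at -1.79 ± 0.28. KO_old 1 had a matrix score of -1.23 beside -0.332 and -0.102, and KO_young 3 one of 0.685 beside -0.0112 and 0.0093. Complexes II to IV had 5 of 29 down and 1 up (17 and 1 over the list alone, median -0.21, adjusted p = 1.00e-05, adjusted p = 0.538 with an estimated correlation). Cox7a1 was at -0.73 ± 0.14 and the assembly gene Surf1 at 0.38 ± 0.08. Complex I had 3 of 34 down (12 over the list alone, median -0.21, adjusted p = 1.00e-05, adjusted p = 0.541 with an estimated correlation), such as Ndufc2 (-0.46 ± 0.11). KO_old 1 carried much of both falls, with a complex I score of -0.631 beside -0.378 and -0.312 in its replicates. Its score for complexes II to IV was -0.651 beside -0.447 and -0.381. ATP synthase had 0 of 16 past the test or over the list alone (median -0.18, adjusted p = 0.00287, adjusted p = 0.541 with an estimated correlation), a call that ended without KO_old 1 (0.0730). Glycolysis genes had 2 of 27 down and 1 up (11 and 1 over the list alone, median -0.13, adjusted p = 0.00867, adjusted p = 0.538 with an estimated correlation). The lactate exporter gene Slc16a3 was at -1.09 ± 0.13 and Pdk4 at 1.29 ± 0.26. Endothelial and angiogenesis genes had 5 of 25 down (6 over the list alone, median -0.15, adjusted p = 0.00485, adjusted p = 0.538 with an estimated correlation). Pdgfrb was at -0.95 ± 0.15 and Cdh5 at -0.71 ± 0.13. The list lost its call without KO_young 3 (0.0608). Fast fibre genes had 2 of 19 down, Gpd1 (-0.74 ± 0.21) and Eya1 (-0.39 ± 0.11), 4 over the list alone and a median of -0.07 (adjusted p = 0.0489, adjusted p = 0.538 with an estimated correlation). The list lost the call, with 0.0506 to 0.0844, without WT_young 1, 2 or 3, KO_young 1 or 2, WT_old 2 or KO_old 1.

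Neuromuscular junction and denervation-responsive genes had 6 of 28 up and 3 down (7 and 3 over the list alone) with a median of -0.01, a mean of 0.11 and no list call (adjusted p = 0.485). Myh3 (2.15 ± 0.15, adjusted p = 2.07e-05), Chrna1 (0.78 ± 0.09, adjusted p = 0.000625) and Gadd45a (1.74 ± 0.29) rose. Calcium genes had 5 up and 4 down (median -0.12, mean 0.05, adjusted p = 0.221), with Camk2b at 0.84 ± 0.10 and Camk2a at -0.85 ± 0.17. In the insulin list Irs1 (-1.15 ± 0.19) and Ptprf (-1.20 ± 0.22) fell and Tbc1d4 (0.77 ± 0.16) rose (median 0.02, mean -0.03, adjusted p = 0.546). In the circadian list Nr1d1 (-0.88 ± 0.14) fell and Cry2 (1.09 ± 0.21) rose (median -0.18, adjusted p = 0.263). Eda2r (1.62 ± 0.27) rose and Cdkn2b (-0.76 ± 0.14) fell in the senescence list (median 0.12, adjusted p = 0.221). Camera called 16 of 31 lists, 9 up and 7 down, camera with an estimated correlation 0 and fry 9. Directional fry ended the matrix, complex I, ATP synthase, endothelial, atrophy, macrophage, adipocyte, cytokine and interferon calls, and mixed fry the macrophage and adipocyte calls. Testing brighter genes alone ended the cytokine (0.0586), interferon (0.0524) and fast fibre calls (0.109), and quantile normalization again the fast fibre call (0.0599). The count of 1868 genes became 3602 with every probe set tested, 2946 at an adjusted p of 0.10, 617 with the knock-out arrays alone, 965 without KO_young 2 and 833 without KO_young 3. The 18S probe sets were lower by -1.09, -1.29 and -1.50 here too.

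Of the 659 genes that passed with age in wild-type muscle and the 1868 in knock-out muscle, 479 passed in the same direction in both. Sln, Krt18, Cpne2, Ankrd1 and Myh3 were among 220 genes that rose with age in wild-type and knock-out muscle (14.6 by chance). Kera, Col1a1, Wif1, Tnmd, Chad and Fmod were among 259 that fell in both (19.4 by chance). In opposite directions 2 genes passed (33.7 by chance), Tph1 (0.51 in wild-type, -0.55 in knock-out) and Hmga2-ps1 (0.80, -0.50), named after their values were seen. The wild-type means of Tph1, 5.38 in young and 5.89 in old muscle, lay under the floor of 6.22. Across genes, which are not independent replicates, the age differences correlated with Pearson 0.674 and Spearman 0.544. The sign was the same in the other genotype for 651 of the 659 wild-type calls and 1804 of the 1868 knock-out calls. With the 12 arrays no gene passed the interaction (37 without KO_old 3, 1 without WT_old 2), so a larger age effect in knock-out muscle is not shown for any 1 of them. The overlap of 479 became 317 without KO_young 2, 279, 205 and 231 without WT_old 1, 2 and 3, and 277, 227 and 179 without WT_young 1, 2 and 3.

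Kcng4 and Fndc5, which fell with the knock-out in young muscle, also fell with age in wild-type muscle (-1.36 and -0.79). Tph1 (0.51, between wild-type means under 6.22), Lrp11 (0.86) and Lonrf1 (0.59) rose in both. In total 3 genes rose and 3 fell in both comparisons (0.115 and 0.552 by chance) and 0 went opposite ways, among 659 and 35 called by limma. Pearson was 0.186 and Spearman 0.185 over genes, which are not independent replicates. Both differences subtract the same 3 young wild-type arrays, and 100 simulated draws with no true effect gave a Pearson of 0.501 (0.474 to 0.532) and a Spearman of 0.473 from that sharing alone. The simulated genes varied independently, so the range leaves out the spread that genes varying together would add. The draws also held no effects, whereas effects of age or genotype widen the differences and can lower a correlation at the same sharing. Whether the lower observed correlations lie outside what sharing gives therefore cannot be judged from these draws. The covariance was 0.00962 beside a simulated 0.0105, a difference of -0.000836. The same sign held for 56.2% of genes beside 66.7% simulated, a share that effects in 1 comparison alone can also lower. With 3 controls no split into parts of 2 or more was possible, so part of the shared count of 6 may come from the shared controls. The count was 10 with probe sets averaged and 13 with brighter genes alone. Leaving out WT_young 1, 2 and 3 gave 10, 0 and 0, and KO_young 1, 2 and 3 gave 0, 1 and 0. Leaving out WT_old 1, 2 and 3 gave 1, 1 and 0, and KO_old 1, 2 and 3 gave 34, 3 and 8. The Pearson moved to 0.103 without KO_young 1 and 0.315 without WT_young 1.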

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

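Tests of other cells and RNA integrity for the mitochondrial lists, of the 3 collagens, of RNA preparation and of fat tissue were chosen after the result was seen.

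Camera called complex I, complexes II to IV, ATP synthase and the tricarboxylic acid cycle lower in knock-out muscle at both ages, but not with an estimated correlation (adjusted p = 0.213 to 0.359 with an estimated correlation), and 3 of 10 splits called as many lists at either age. RNA from other cells would open no gap between the genes of muscle fibres if it lowered them alike, which was assumed and not tested. The mitochondrial score lay below the fast fibre score in 6 of 6 knock-out arrays, the smallest gap being -0.282. In wild-type arrays the gap was between -0.0467 and 0.0179. In old muscle the fast fibre scores were lower too, at -0.256, -0.0844 and -0.0599 in knock-out and -0.0539, -0.0220 and -0.0422 in wild-type arrays. A part played by RNA from other cells therefore stays open. The 97 mitochondrial genes had medians of -0.27 and -0.38 for genotype in young and old muscle and the 19 fast fibre genes 0.02 and -0.04. A difference in RNA integrity is not settled, because the change with age used as the yardstick also holds ageing and RNA preparation. The 5' to 3' difference moved more with age in wild-type muscle (Actb 0.160, Gapdh 0.166) than with genotype in young muscle (0.0899 and 0.0222). With genotype in old muscle it moved by 0.115 for Actb and 0.00623 for Gapdh. The mitochondrial genes moved with age in wild-type muscle by a median of -0.08, 28.1% of the young genotype effect. A biological effect of the labelled genotype may remain as a hypothesis, since batch and litter are not given.

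Col1a1, Kera, Tnmd, Chad and Fmod fell with age in both genotypes, while of 5 fibrillar collagens 1 fell in wild-type and 2 in knock-out muscle, and of 4 other tendon markers 1 in each. A smaller share of fibroblasts stays open: 14 other fibroblast markers had medians of -0.46 and -0.61 with age in wild-type and knock-out muscle, and 3 fibrillar collagens not named for their fall -0.75 and -0.79, with a gap that grew by 0.381 and overlapped between young (-0.418 to 0.306) and old arrays (-0.250 to 1.38). The gap to 5 fibrillar collagens grew by 1.22 and that of the 4 other tendon markers (medians -0.16 and -0.58) to the named tendon genes (-2.23 and -3.39) by 2.42, but Col1a1, Col1a2 and the named tendon genes were picked for their fall, so these gaps decide nothing about fibroblasts or about less tendon, which cannot be told apart from age here. A different RNA preparation of the old samples cannot be told apart from age, because the 18S probes were -1.51 lower in the old arrays (11.7 to 12.8 beside 13.2 to 14.2). Age itself stays open as a biological explanation.

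Adipocyte markers had a higher genotype effect in old than in young muscle, with a median difference of 1.10 (adjusted p = 0.673 with an estimated correlation), although fry did not call the list and 0 of 19 members passed. Fat tissue in some samples may account for it: the lowest old knock-out array scored -0.645, below old wild-type arrays (-0.553 to -0.0582), while 2 old knock-out arrays lay above every old wild-type array, with 4 of 5 abundant adipocyte genes highest there. No biological explanation was tested apart from this.

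The other lists whose genotype effect differed between the ages by camera had median differences of 0.32 (macrophage), 0.21 (atrophy), 0.16 (interferon), 0.11 (slow fibre), 0.10 (antioxidant), -0.10 (complex I), -0.11 (complexes II to IV), -0.11 (glycolysis), -0.12 (calcium handling) and -0.19 (neuromuscular junction). Exchanging genotype within age gave as many called lists in 35 of 100 splits, so chance is not excluded for these lists (11 called, at most 20 in another split).

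The 18S control probes, outside the gene tests, were lower with age by a mean of -1.73 in wild-type and -1.29 in knock-out muscle. Among the 10092 probe sets apart from controls that name no gene or several, also outside the gene tests, 1, 11, 96 and 458 passed limma for genotype in young muscle, genotype in old muscle, age in wild-type muscle and age in knock-out muscle.

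For genotype in young muscle 35 genes passed and at most 0 in another of the 10 splits, 241 and at most 1 for genotype in old muscle, 659 and at most 0 for age in wild-type muscle, and 1868 and at most 0 for age in knock-out muscle, with 1 split, the real one, as large in each. For lists the real values were 13, 13, 8 and 16 and the highest others 16, 15, 9 and 15, with 3, 3, 4 and 1 splits as large. In these 4 comparisons 10 splits are too few for a share under 0.05. For the interaction the real count is 0, so each of the 100 splits gave as many genes by construction (100 of 100, at most 11), which decides nothing. For the overlap of genotype effects (25, at most 0 in another split) and of age effects (479, at most 2) 1 of 100 splits, the real one, was as large. Other splits of a single comparison called at most 1 gene, so these overlaps had almost nothing to share and add little to the single comparisons. Chance is not excluded for the resemblance of ageing to the young genotype effect, where the covariance beyond that of the shared arrays was -0.000801 and at most 0.0310 in another split, 52 of 100 being as large.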

How the results depend on the processing

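Leaving out KO_old 1 and WT_young 1 together was chosen after seeing the data. Background signal limits changes in dim genes, and 3 arrays per group limit the precision. No paired analysis was possible because the labels give no numbers that tie an array of one group to an array of another, and the replicate numbers used here are names. The cause was not tested for the changes below, except where fewer or more genes or arrays entered. Of 400 results for Ppargc1a probe sets over the settings, 397 kept their side of the threshold, and 3 passed with age in wild-type muscle. Of the named genes 5819 results were the same, 635 lost the call, 229 gained it and 0 reversed, and of the lists 2452, 198, 132 and 3. A change of direction was counted as a reversal only where the result passed with the main settings or in the setting tried. Calls held in each setting for 1 of 21, 0 of 47, 27 of 49 and 43 of 76 named genes in the 4 comparisons. The 0 of 47 was fixed by 1 setting, only the groups compared, which called no gene for genotype in old muscle.

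With brighter genes alone the 35 genes of the young genotype effect became 65, the 241 of the old one 372, the overlap of genotype effects 44 instead of 25, the correlation of age effects 0.726 instead of 0.674 and the resemblance count 13 instead of 6 (10 with the mean of probe sets). Quantile normalization again gave 56 young genotype genes and an overlap of 39, and centred arrays gave 48.5% risen of the old genotype genes instead of 35.7%. Trended and robust variances gave 104 and 389 genotype genes in young and old muscle, and array weights 1019 young genotype genes (38.4% risen instead of 20.0%) and 2451 age genes in wild-type muscle. An adjusted p of 0.10 gave 119, 800, 1112 and 2946 in the 4 comparisons. Testing every probe set gave 1116 and 3602 for age in wild-type and knock-out muscle, and only the groups compared gave 0 for genotype in old and 617 for age in knock-out muscle. Without both arrays that stood apart 216 young genotype genes passed. The interaction gave 0 genes by limma in the settings that kept the 12 arrays and without both arrays that stood apart. Camera with an estimated correlation called 0 lists in each comparison, fry 8, 4, 4, 9 and 0 and mixed fry 12, 18, 20, 26 and 0, beside 13, 13, 8, 16 and 11.

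Leaving out 1 array gave 1 to 173 genes (genotype, young), 28 to 644 (genotype, old), 208 to 1093 (age, wild-type), 833 to 1998 (age, knock-out) and 0 to 37 (interaction, 37 without KO_old 3, 1 without WT_old 2), overlaps of 1 to 61 and 179 to 649 with correlations of 0.277 to 0.496 and 0.598 to 0.710, and for the resemblance 0 to 34 genes, a correlation of 0.103 to 0.315 and a covariance of -0.00449 to 0.00499. Lists called ranged over 11 to 15, 13 to 16, 6 to 13, 14 to 17 and 8 to 16. The matrix list reversed to -0.0250 for genotype in young muscle without KO_young 3 (up to 0.407), and the interferon list without WT_young 1 to 0.0886 for genotype in young muscle (from -0.129) and 0.0907 for age in wild-type muscle (from -0.132).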

Other observations

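The tests here were chosen before the result was seen. Genes near the targeted locus could differ between genotypes because of sequence that came with the targeted allele. Among the 100 tested genes nearest to Ppargc1a (GRCm38.p6), 1 passed a genotype test, Evc (-0.25 in young and -0.90 in old muscle, chosen after its values were seen). Across 16135 windows of as many genes the median was 1 and the highest 7, and 74.9% held at least 1, so the neighbourhood holds no excess of called genes.

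Strain segments that differ between the age groups could leave neighbouring genes changed together, since the labels give a mixed background. Among the 479 genes that passed for age in both genotypes, 9 neighbouring pairs moved the same way, against a mean of 5.80 and a highest of 16 in 10000 permutations (p = 0.127), which leaves such segments open. Prelp and Fmod, both matrix genes, and Thra and Nr1d1, which overlap in the genome, were among the pairs, chosen after their values were seen. Cyfip2, a gene of the substrain list, rose with age by 1.41 in wild-type and 1.41 in knock-out muscle, while its list was not called in either (adjusted p = 0.0776 and 0.332). A rise of 1 gene cannot tell a strain difference between the age groups from an effect of age.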
